A study of Homo sapiens with 8 samples.

How the data were processed

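Per the labels' protocols, total RNA depleted of ribosomal RNA was made into stranded libraries from primary human lung fibroblasts, 8 libraries in 4 groups of 2. Per the submitters' processing notes, the authors used Salmon, DESeq2 and the genome GRCh38.p12; tool versions are not given in the sources used here. The deposited table holds one normalized signal per gene and library, which is not a count; how it was normalized is not given in the sources used here. Low values were multiples of what 1 read is worth for 56% to 68.3% of values at a tolerance of 0.1, so whole reads were not recovered and no count model was run.

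The table had 56135 entries. Of these 1303 named no gene (0.0795% to 0.107% of a library's total) and were kept out of gene tests. XIST, TSIX and Y-linked genes, 366 entries, were left out of every table and test. The library totals include both kinds of entries. The 1837 entries that shared 211 names were summed by name, which gave 52840 names, 28178 of them above 0 in a library; 20100 names matched the GENCODE 29 annotation, from which the coordinates were taken. Libraries had 18464 to 22010 genes above 0, and the top 10 genes took 66.2% to 79.8% of a total. Common genes were also listed at 0 in some libraries, so a 0 can be a failed estimate and such genes are given library by library. 

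Values were tested as log2(value + 1) with limma 3.58.1 (trend, moderated by empirical Bayes) in R 4.3.3, on genes with a mean of 10 or more over the 8 libraries, 13486 genes. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and errors of differences are SE. These SE come from the fit without the culture, also where a call comes from the fit with the culture as a block. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The additive effects of RGCC and of TGF-beta came from a model with both factors, and the effects in each state and the interaction from a model with 4 group means, all 8 libraries sharing one spread. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists with at least 2 members, and again with an estimated correlation; fry tested whether a set moved on balance. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and drawn with matplotlib 3.10.9.

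The groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The 32 lists held TGF-beta and SMAD targets, collagens and other matrix proteins, collagen processing, contractile genes, matrix-degrading proteases, protease inhibitors, G1/S genes, G2/M genes, p53 targets, histones, interferon-stimulated genes, inflammatory cytokines, the unfolded protein response, amino acid synthesis, cholesterol synthesis, hypoxia, NRF2 targets, BMP and ID genes, immediate early genes, complement, lipofibroblast genes, the Wnt pathway, heat shock genes, fibroblast identity genes, markers of epithelial, endothelial, leukocyte, pericyte and mesothelial cells, mitochondrially encoded genes, ribosomal proteins and nuclear-retained transcripts. Named genes were RGCC, then for each comparison the 5 largest rises and 5 largest falls among called genes with a mean of 50 or more and one sign in both cultures, or, where fewer than 10 passed, the 10 with the smallest p. The same was drawn from the fit with the culture as a block. Up to 4 members with the smallest p were added from each list with a called member, and so were COL1A1, COL1A2, COL3A1, FN1, ACTA2, MMP3, TIMP1, CDK1, CCNB1, CDKN1A, TGFB1, SMAD7 and IL6; other genes fixed there were not analysed here. Genes with clone names were counted and not named.

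The culture numbers in the source names pair the samples. Deviations from the group means in same-numbered libraries correlated across genes, which are not independent replicates, at 0.152 to 0.244 in 6 pairs of groups, each above 0.1. The fit without the culture was kept as planned, and the blocked result is given where it changes the call of a named gene, or of a list in the comparisons over both factors and the interaction. On simulated data with 13378 genes and 50 changed per fold, the RGCC comparison called 6%, 54%, 78% and 90% of genes changed 2-, 4-, 8- and 16-fold, with 5 false calls. The TGF-beta comparison, simulated with 13376 genes, called 2%, 52%, 80% and 90%, with 7 false calls. Of 20 lists of 25 genes shifted by 0.7 and 20 unshifted, camera called all 20 shifted and 0 unshifted with either correlation. The simulated genes varied independently, without effects of culture or library set. It therefore cannot tell how often camera with the preset correlation calls unshifted lists whose genes vary together. Alternatives were a pseudocount of 8, no filter, a mean of 50 or more, quantile normalization, the culture as a block, each library left out in turn, and, added later, leaving out the shallowest libraries and a term for the library set.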

Results

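RNA was sequenced from primary human lung fibroblasts, the matrix-producing cells of the lung, that had been electroporated with a plasmid encoding RGCC (regulator of cell cycle) or with NULL, a plasmid without a coding insert. The cells were then left without or treated with recombinant TGF-beta, the cytokine that drives fibroblasts toward matrix production and contraction, for 24 h. The 4 groups were NULL alone, NULL with TGF-beta, RGCC alone and RGCC with TGF-beta, each with 2 libraries that the source names number as cultures 1 and 2. The labels do not say whether these cultures came from separate donors, so the p-values may measure technical spread only. The design asks what RGCC changes in resting and in TGF-beta-treated fibroblasts, and whether it alters the response to TGF-beta.

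The normalized values of a library summed to 22.6 to 49.8 M. From the steps between low values, 1 read was worth 0.623 to 1.73 units, which puts the libraries at an estimated 26.3 to 51.1 M assigned reads. RN7SL1 and RN7SL2, the RNA components of the signal recognition particle, together took 43.5% to 53.1% of the total. Protein-coding genes took 16.4% to 29.8%, or an estimated 4.57 to 11.8 M reads. The lowest of these were 4.57 M in RGCC alone, culture 2, and 4.78 M in NULL with TGF-beta, culture 1. The first principal component of the tested genes carried 27.3% of the variance and the second, which separated the cultures, 21.9%.

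Table entries without a gene name, kept out of every test of genes, divided the libraries into sets that partly followed the groups. Over the 210 such entries with a mean of 10 or more, the libraries formed 3 sets. Set A held both NULL alone libraries and culture 1 of NULL with TGF-beta. Set B held culture 2 of NULL with TGF-beta and both RGCC with TGF-beta libraries, and set C both RGCC alone libraries. Pearson's r across these entries, which are not independent replicates, was 0.834 to 0.943 in the 7 pairs of one set and -0.32 to -0.0413 in the 21 pairs across sets. RGCC could therefore be compared within set B (TGF-beta-treated cells) and TGF-beta within set A (NULL plasmid), each with a lone library on one side. This leaves the cultures unequal, so values within a set are followed in parentheses by those of 1 culture alone, culture 2 in set B and culture 1 in set A, with 1 library on each side. The RGCC effect in resting cells (A against C) and the TGF-beta effect with RGCC (C against B) could not be separated from the sets. The same holds for the interaction, which contains both. NULL with TGF-beta was the only group divided between sets. The effects of RGCC and of TGF-beta over both levels of the other factor therefore also set libraries of different sets against each other.

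**Figure D1:**
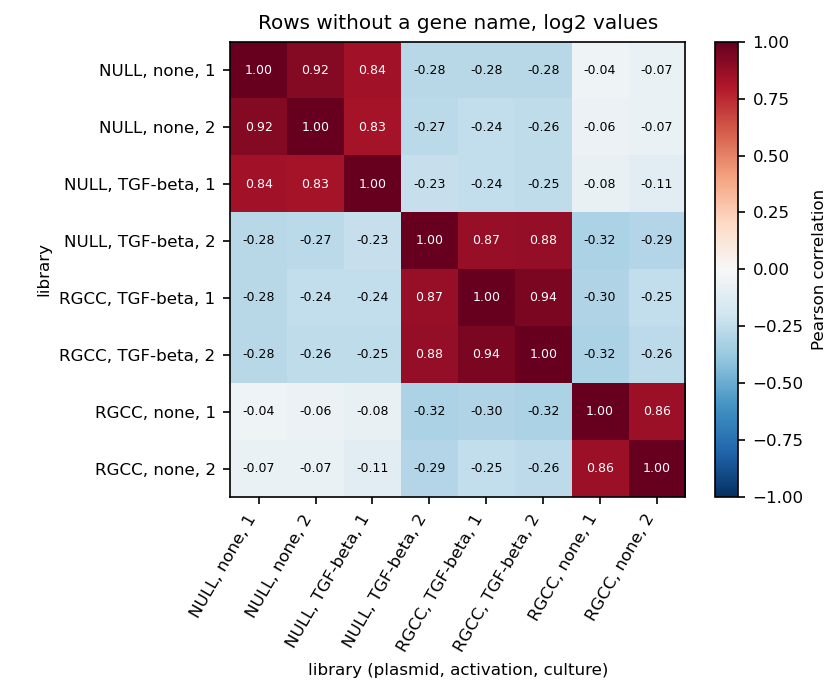
Heat map of Pearson's r (color scale, no unit) between the 8 libraries, named by plasmid, treatment and culture on both axes, over 210 table entries without a gene name. Pairs of the same set lie at 0.834 or above and pairs of different sets at -0.0413 or below.

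RGCC (chromosome 13, 41457559 to 41470882, plus strand, GRCh38) was high in each library that received its plasmid. Its normalized values were 475 and 1069 with RGCC alone and 622 and 1489 with RGCC and TGF-beta. In the NULL libraries RGCC was listed at 0 in all but culture 2 of NULL alone, at 2.89. The other gene that rose was GH1 (chromosome 17, 63917200 to 63918838, minus strand), which encodes pituitary growth hormone. Sequence carried by the RGCC plasmid was not excluded as the source of the GH1 reads. GH1 went from 49.7 ± 2.53 (SD, n = 2) to 2316 ± 355 in resting cells and from 48.5 ± 0.0315 to 2444 ± 1575 in TGF-beta-treated cells, 44.7-fold over both states on the log2(value + 1) scale. By limma the differences passed the threshold for RGCC (9.21 ± 0.57 log2, SE, adjusted p = 0.000178) and for GH1 (5.48 ± 0.30, adjusted p = 0.000111), with the same sign in both cultures. Within set B they were 9.91 (10.54) for RGCC and 5.46 (6.17) for GH1, and with the set as a term the call of GH1 ended (adjusted p = 0.0527).

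**Figure D2:**
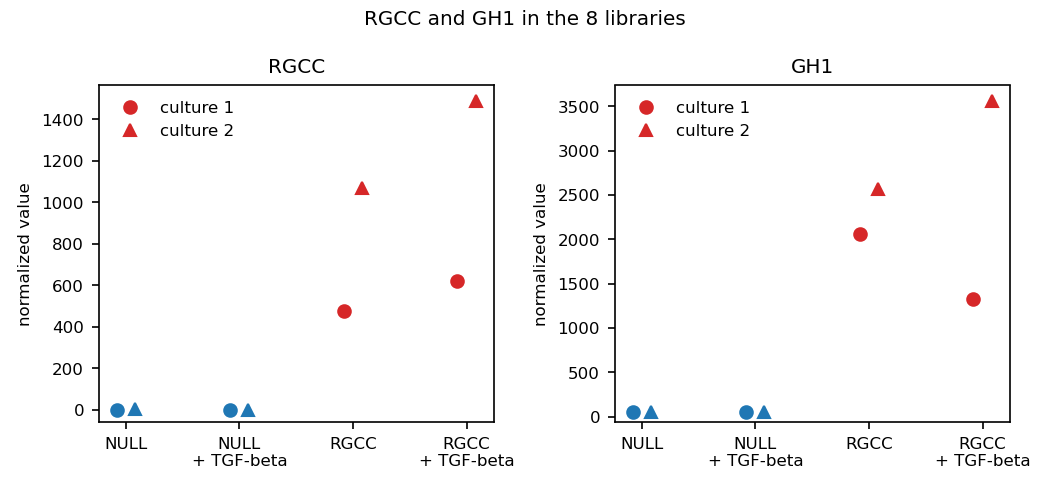
Normalized value of RGCC and of GH1 (y axis, linear scale) in each library by group (x axis), NULL in blue and RGCC in red, circles for culture 1 and triangles for culture 2. RGCC lies at 475 to 1489 and GH1 at 1330.3 to 3558 in the libraries with the RGCC plasmid, above each NULL library.

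Across both states, RGCC and GH1 were the 2 genes called among 13486 tested, and no gene was called lower. The genes next in rank did not pass the test. They included ARID2, a subunit of the PBAF chromatin remodeling complex (-4.10 ± 0.66, 34 ± 6.57 with NULL and 1.83 ± 1.85 with RGCC in resting cells), ACBD6, an acyl-CoA-binding protein (-2.66 ± 0.45), and FANCG of the Fanconi anemia DNA repair pathway (-1.31 ± 0.23). The glycolytic enzyme ALDOC (-1.27 ± 0.24), the histone variant gene H2AFZ (-2.92 ± 0.56), HIST3H2BB (-1.22 ± 0.23), the lipid-binding SEC14L2 (-1.04 ± 0.20) and RGAG1 (1.62 ± 0.32) followed, with limma adjusted p of 0.515 to 0.606. Of the genes fixed in advance, TIMP1, an inhibitor of matrix metalloproteinases, differed by -0.89 ± 0.26, COL3A1 by -1.24 ± 0.46, fibronectin (FN1) by -0.56 ± 0.23, COL1A1 by -0.27 ± 0.24 and smooth muscle actin (ACTA2) by -0.42 ± 0.42, none past the threshold. An unadjusted p under 0.05 was reached by 984 genes (1385 with the culture as a block), against 674 expected by chance. With the library set as a term 6 genes were called higher, 1 of them shared, which was RGCC. That fit compares 2 RGCC libraries with 1 NULL library, all of set B, and takes its spread from all groups, so it carries little weight.

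Among the 31 gene lists tested, interferon-stimulated genes, the antiviral genes downstream of interferon, stood higher with RGCC. Of the 28 members 27 were positive, with a median log2 difference of 0.64; none was called over all genes, and 7 were higher when adjusted over the list alone. Examples chosen after their values were seen were IFIT2 (1.83 ± 0.43) and MX2 (0.86 ± 0.27), which restrict virus replication, and the oligoadenylate synthetase OAS2 (0.72 ± 0.21). The p53 target genes, which answer to DNA damage, had 17 of 21 members positive and a median of 0.31, with 1 higher when adjusted over the list alone. By camera with a preset correlation of 0.01 the lists passed at adjusted p = 3.62e-10 and 0.00122. Both calls were lost at adjusted p = 0.162 with an estimated correlation for the interferon list and 0.162 for the p53 list. Medians by culture were 0.52 and 0.59 for interferon genes and 0.18 and 0.33 for p53 targets, and within set B 0.71 (0.74) and 0.44 (0.35).

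The list of replication-dependent histone genes, transcribed in S phase, stood lower with RGCC. 11 of the 12 members were negative, with a median of -0.70. The exception, H1F0 (0.48 ± 0.18), is a linker histone gene whose expression is not tied to replication; adjusted over the list alone, 7 were lower and 1 higher. Histone genes outside the list had the smallest p after RGCC and GH1 in the fit with the culture as a block, among them the linker histone HIST1H1B (-1.91 ± 0.47), HIST1H2BH (-1.60 ± 0.42), and HIST1H2BE (-1.57 ± 0.45). The others were HIST1H2BO (-1.69 ± 0.49), HIST1H2BL (-1.60 ± 0.47), HIST1H2BM (-1.53 ± 0.47), HIST1H4A (-1.64 ± 0.52) and HIST1H4I (-1.60 ± 0.58), none past the threshold (lowest blocked limma adjusted p = 0.0552). The H2B and H4 genes among them are near-identical copies, so their single values are uncertain. The SE given are those of the fit without the block. The list passed camera at adjusted p = 9.81e-06, and 0.285 as an adjusted p with an estimated correlation. The culture medians were -0.56 and -0.75, and the median within set B -1.11 (-0.87). Genes of G2/M and mitosis had a median of -0.57, adjusted p = 0.00163, and 0.484 with an estimated correlation, and genes of G1/S and DNA replication -0.53, adjusted p = 0.00694, and 0.372 with an estimated correlation. Their culture medians were -0.068 and -1.26, and -0.056 and -0.82. CDK1, the mitotic kinase, was listed at 27.5 and 87.3 with NULL alone, 4.66 and 34.5 with NULL and TGF-beta, 0 and 45.9 with RGCC alone and 0.992 and 0 with RGCC and TGF-beta.

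Cholesterol synthesis genes were lower with RGCC in 19 of 19 members, by a median of -0.56, adjusted p = 2.26e-07, and 0.254 with an estimated correlation. Among members chosen after their values were seen, the sterol reductase DHCR7 differed by -1.19 ± 0.34 and the sterol isomerase EBP by -0.79 ± 0.27. Over all genes none of the list was called, and adjusted over the list alone 0 were. Collagens and other matrix proteins had 25 of 31 members negative, with a median of -0.45, adjusted p = 0.000358, and 0.254 with an estimated correlation. That median averages both states. Of the matrix genes fixed in advance, COL1A1 differed by 0.21 in resting cells, COL1A2 by -0.32, COL3A1 by -0.92 and FN1 by -0.54. With TGF-beta they differed by -0.76, -0.81, -1.56 and -0.57, none past the threshold in either state. Collagen processing and crosslinking genes had a median of -0.35, adjusted p = 0.000174, and 0.254 with an estimated correlation. Hypoxia and glycolysis genes had -0.30, adjusted p = 0.00188, and 0.254 with an estimated correlation, and contractile and myofibroblast genes -0.32, adjusted p = 0.0129, and 0.444 with an estimated correlation. Within set B the medians were -0.95 (-0.54) for cholesterol synthesis, -0.61 (-0.52) for matrix proteins, -0.46 (-0.24) for collagen processing, -0.40 (-0.42) for hypoxia and -0.86 (-0.50) for contractile genes. The lists passed camera with the preset correlation and none kept the call with an estimated one.

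Mitochondrially encoded genes, of which 13 of 13 were negative, had a median of -0.60, adjusted p = 9.81e-06, and 0.415 with an estimated correlation, but the cultures differed, at -1.35 in culture 1 and 0.13 in culture 2, and the median within set B was -0.13 (0.30). Ribosomal proteins had a median of -0.24, adjusted p = 0.0025, and 0.484 with an estimated correlation, and 0.10 (-0.042) within set B. Fibroblast identity genes had a median of -0.35, adjusted p = 0.00545, and 0.254 with an estimated correlation, with 1 member lower when adjusted over the list alone, and -0.68 (-0.28) within set B. Leukocyte markers, 4 members, had a median of -0.72, adjusted p = 0.0407, and 0.285 with an estimated correlation, and -0.96 (-0.33) within set B. Immediate early genes missed the threshold at adjusted p = 0.0677 and passed it with the culture as a block at 0.041 (median 0.17), and lost that call with an estimated correlation (blocked adjusted p = 0.379). Of 15 alternatives, a list call was lost with its sign kept in 8 for leukocyte markers, 4 for ribosomal proteins, 3 each for G2/M, G1/S and contractile genes, and 1 each for mitochondrial, hypoxia, fibroblast identity and p53 genes.

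**Figure D3:**
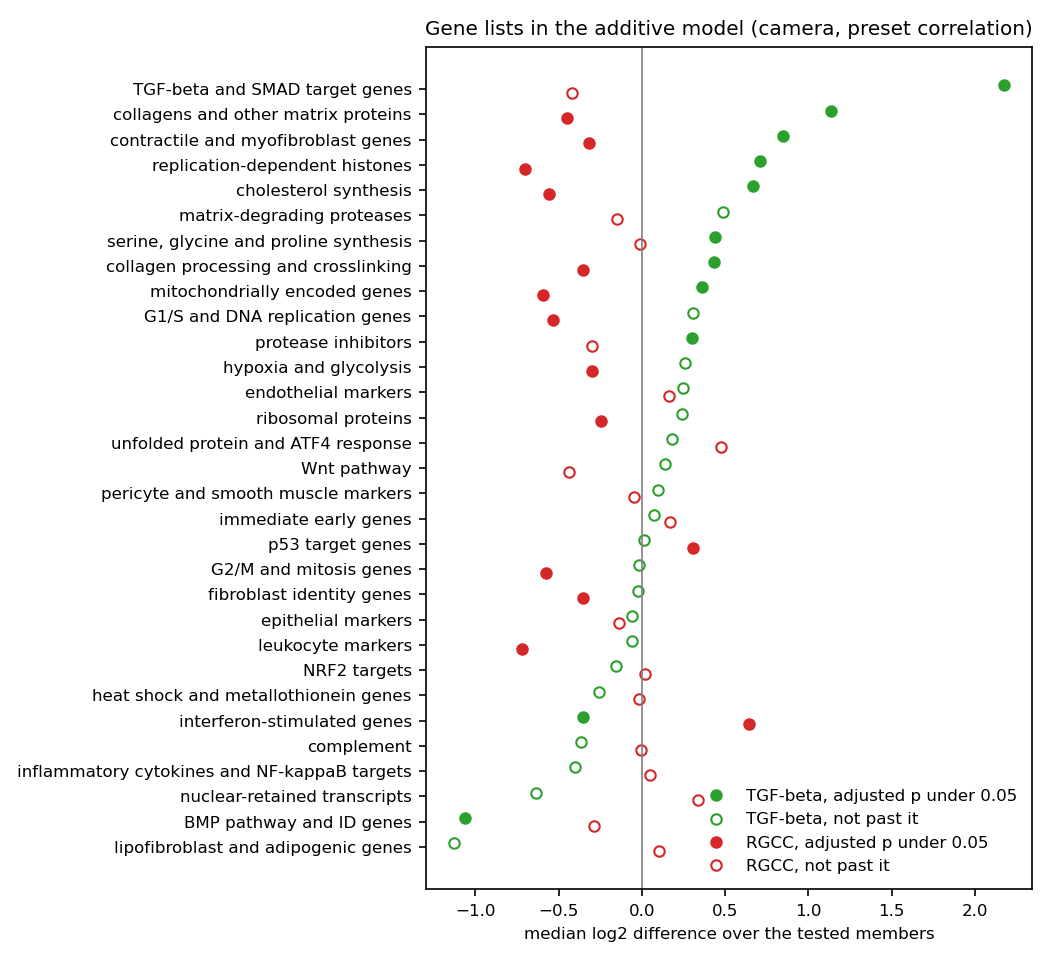
Median log2 difference (x axis) of each tested gene list (y axis) with TGF-beta (green) and with RGCC (red), over both levels of the other factor in 8 libraries; filled points passed camera with the preset correlation at an adjusted p under 0.05. Interferon-stimulated genes lie at 0.64 with RGCC and -0.35 with TGF-beta, and matrix proteins at -0.45 and 1.14.

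In resting cells, a comparison of library set A with set C, 4 genes were called, 2 higher with the RGCC plasmid (RGCC and GH1) and 2 lower. RGCC rose by 8.50 ± 0.78 (limma adjusted p = 0.0215) and GH1 by 5.51 ± 0.45 (adjusted p = 0.0159). The call of RGCC was lost in 8 alternatives and that of GH1 in 7. ARSI, an arylsulfatase, was lower and listed at 0 in both RGCC alone libraries. Its values were 55.1 and 35.8 with NULL alone, 109 and 119 with NULL and TGF-beta, 0 and 0 with RGCC alone and 52.2 and 104 with RGCC and TGF-beta (limma adjusted p = 0.0304). The other lower gene bears a clone name. Not called were FAT3, an atypical cadherin (3.14 ± 0.60), KDELR1, a receptor returning proteins to the endoplasmic reticulum (1.79 ± 0.36), GTF3A, a transcription factor of 5S RNA genes (-1.72 ± 0.36), and TCEAL8 (-3.46 ± 0.75), at adjusted p of 0.978 to 1. GMEB2, TGIF2-C20orf24, DSTYK, NINL and HJURP were also among the smallest p and not called; each was listed at 0 in at least one library. GMEB2 was listed at 0 and 0 with NULL alone, 31.4 and 65 with NULL and TGF-beta, 61.4 and 23 with RGCC alone and 30.9 and 11.4 with RGCC and TGF-beta. DSTYK, a kinase, was at 20.3 and 94.3 with NULL alone, 37.5 and 13.6 with NULL and TGF-beta, 0 and 0 with RGCC alone and 18.2 and 7.43 with RGCC and TGF-beta. The readthrough gene TGIF2-C20orf24 was at 0 and 0 with NULL alone, 61.1 and 70.8 with NULL and TGF-beta, 77.6 and 12.2 with RGCC alone and 88.4 and 48.3 with RGCC and TGF-beta. NINL was at 33.9 and 59.4 with NULL alone, 27.7 and 37.8 with NULL and TGF-beta, 3.81 and 0 with RGCC alone and 45.9 and 40.4 with RGCC and TGF-beta. HJURP, a centromere histone chaperone, was at 12.8 and 41.5 with NULL alone, 15.9 and 74.1 with NULL and TGF-beta, 0 and 0 with RGCC alone and 10.4 and 28 with RGCC and TGF-beta. The number of calls was 0 without culture 1 of NULL alone or culture 1 or 2 of NULL with TGF-beta and 1 without culture 2 of NULL alone or culture 1 or 2 of RGCC with TGF-beta; that of ARSI was lost in 12 alternatives. An unadjusted p under 0.05 was reached by 437 genes (754 blocked), against 674 expected by chance.

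With TGF-beta, 3 genes were called higher with RGCC and 2 lower, 4 and 2 with the culture as a block, and 3 and 1 with quantile normalization. RGCC rose by 9.91 ± 0.78 (limma adjusted p = 0.0085) and GH1 by 5.46 ± 0.45 (adjusted p = 0.0085). The call of RGCC was lost in 4 alternatives and that of GH1 in 3. IL24, a cytokine of the IL-10 family, was listed at 180.3 and 69.5 with NULL alone, 0 and 0 with NULL and TGF-beta, 266 and 206 with RGCC alone and 93.9 and 41 with RGCC and TGF-beta (limma adjusted p = 0.0316). The developmental transcription factor gene HOXA4 was lower at adjusted p = 0.0234, listed at 32.6 and 47.3 with NULL alone, 77.2 and 131 with NULL and TGF-beta, 12.8 and 19.1 with RGCC alone and 0 and 0 with RGCC and TGF-beta. Lamin B1 (LMNB1), a protein of the nuclear lamina, was lower at adjusted p = 0.0358, listed at 81.5 and 45.5 with NULL alone, 116 and 51.3 with NULL and TGF-beta, 87.9 and 118 with RGCC alone and 0 and 0.908 with RGCC and TGF-beta. IDO1, which degrades tryptophan, differed by 2.97 ± 0.44 and passed the test with the culture as a block (blocked adjusted p = 0.0397). Not called were QPRT, an enzyme of NAD synthesis (-5.01 ± 0.73), TECPR1, which acts in autophagy (-3.03 ± 0.44), SAMD9, an antiviral factor (3.31 ± 0.53), HIST1H3F (-2.16 ± 0.70) and HIST1H4I (-1.92 ± 0.86), nor FAN1 and ZNF844. FAN1, a DNA repair nuclease, was listed at 10.2 and 25.3 with NULL alone, 74.3 and 30.6 with NULL and TGF-beta, 38.2 and 19.3 with RGCC alone and 0 and 0 with RGCC and TGF-beta. The zinc finger gene ZNF844 was at 33.4 and 23.9 with NULL alone, 0 and 0 with NULL and TGF-beta, 36.6 and 27.4 with RGCC alone and 30.2 and 17.9 with RGCC and TGF-beta. Within set B the differences were 2.62 (2.83) for IDO1, 2.66 (2.45) for SAMD9 and -3.00 (-2.74) for TECPR1. The count was 2 without culture 1 or 2 of NULL alone or culture 1 of RGCC alone, 24 without culture 2 of NULL with TGF-beta, 0 without culture 2 of RGCC alone and 1 without culture 1 or 2 of RGCC with TGF-beta, and the calls of IL24, HOXA4 and LMNB1 were lost in 12, 11 and 13 alternatives. An unadjusted p under 0.05 was reached by 1158 genes (1728 blocked), against 674 expected by chance.

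TGF-beta changed 126 genes across both plasmids, 98 higher and 28 lower, out of 13486 tested, and 2091 had an unadjusted p under 0.05 (2617 blocked) against 674 expected by chance. IL11, a profibrotic cytokine of the IL-6 family, rose most among the named genes, from 98.4 ± 6.48 to 11772 ± 106 (SD, n = 2) with NULL and from 88.1 ± 37.9 to 5534 ± 1674 with RGCC, 6.44 ± 0.28 on the log2 scale. The list of TGF-beta and SMAD targets, genes that the receptor's SMAD proteins switch on, had 12 of 13 members positive, 7 called and 11 higher when adjusted over the list alone. TGFBI, a secreted matrix adhesion protein, rose by 3.37 ± 0.29, the circadian repressor BHLHE40 by 2.79 ± 0.39, the Wnt ligand WNT5B by 2.18 ± 0.31 and SMAD7, the inhibitor of the pathway, by 1.53 ± 0.23. TGFB1, which encodes the cytokine, differed by 2.54 ± 0.58 and did not pass (adjusted p = 0.0865). By limma the adjusted p ranged from 1.49e-05 for IL11 to 0.0162 for SMAD7. The list passed camera at adjusted p = 2.42e-15 and, alone among the lists, kept the call at adjusted p = 0.00959 with an estimated correlation; its median was 2.18, and 2.43 (2.41) within set A. With the culture as a block 305 genes were called, 226 higher and 79 lower; 126 of them were those of the fit without it. Within set A the differences were 6.88 (6.95) for IL11, 3.17 (3.62) for TGFBI and 2.07 (2.49) for BHLHE40. With the library set as a term 41 genes were called, 10 higher and 31 lower, 11 of them shared. That fit rests on 1 library with TGF-beta against 2 without it in set A, and the 1 library is among the shallowest, so its count carries little weight. Without the shallowest libraries 16 genes were called.

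Of 31 collagens and other matrix proteins, 10 were called higher with TGF-beta, and 17 higher and 2 lower when adjusted over the list alone. The anchoring-fibril collagen COL7A1 rose by 3.20 ± 0.21, COL1A1, the main chain of type I collagen, by 2.17 ± 0.24 (4325 ± 361 to 27135 ± 1344 with NULL), thrombospondin-1 (THBS1), which activates latent TGF-beta, by 2.50 ± 0.33 and fibronectin (FN1) by 1.58 ± 0.23. COL10A1, a collagen of hypertrophic cartilage, was called at adjusted p = 0.00273 and listed at 0.945 and 0.435 with NULL alone, 163 and 71.9 with NULL and TGF-beta, 0 and 0 with RGCC alone and 192 and 40.3 with RGCC and TGF-beta. COL3A1 differed by 1.51 ± 0.46 and COL1A2 by 1.14 ± 0.29, past the threshold with the culture as a block (adjusted p = 0.00962 and 0.0315) and not without it. Of the 21 contractile genes 3 were called and 10 were higher when adjusted over the list alone. TPM1, an actin-binding tropomyosin, rose by 2.31 ± 0.18, transgelin (TAGLN) by 2.11 ± 0.30 and calponin CNN2 by 1.86 ± 0.31, and PALLD, an actin-bundling protein, by 1.03 ± 0.21 in the blocked fit (adjusted p = 0.0396). ACTA2 differed by 0.82 ± 0.42 and did not pass (adjusted p = 0.378). The collagen list had a median of 1.14 (camera adjusted p = 7.96e-13, and 0.0807 as an adjusted p with an estimated correlation) and the contractile list 0.85 (2.72e-07 and 0.317). Within set A the medians were 1.07 (1.23) and 1.09 (1.25), COL7A1 differed by 3.67 (3.66), COL1A1 by 2.70 (2.62), TPM1 by 1.97 (2.11) and TAGLN by 2.20 (2.49).

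Other genes that rose with TGF-beta were AMIGO2, a leucine-rich cell adhesion protein (4.06 ± 0.24), the protease inhibitor SERPINE2 (2.92 ± 0.27), the metalloproteinase inhibitor TIMP3 (1.63 ± 0.26), and the gelatinase MMP2 (1.21 ± 0.21). Also higher were the tight-junction claudin CLDN14 (4.30 ± 0.46), the growth factor receptor PDGFRB (1.77 ± 0.26), and the cytokine LIF (2.60 ± 0.39). So were CSF1R, the receptor of macrophage colony-stimulating factor (2.62 ± 0.40), the Wnt regulator DACT1 (4.20 ± 0.72) and the collagen chaperone SERPINH1 (1.16 ± 0.21). Those that fell were RASL11A, a Ras-like GTPase (-3.41 ± 0.28), reelin (RELN, -2.96 ± 0.40), the monocarboxylate transporter SLC16A6 (-3.47 ± 0.62), IDO1 (-2.80 ± 0.42), and TCF21, a transcription factor of lung mesenchyme (-1.78 ± 0.27). WDCP was lower at adjusted p = 0.0377, and was listed at 72.9 and 102 with NULL alone, 0 and 3.89 with NULL and TGF-beta, 127 and 83 with RGCC alone and 19.7 and 17.5 with RGCC and TGF-beta. All of these had limma adjusted p between 0.000128 and 0.0377 and one sign in both cultures. The count of called genes was 41 without culture 1 of NULL alone, 44 without culture 2 of NULL alone, 52 without culture 1 of NULL with TGF-beta, 50 without culture 2 of NULL with TGF-beta, 69 without culture 2 of RGCC alone, 475 without culture 1 of RGCC with TGF-beta and 54 without culture 2 of RGCC with TGF-beta.

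A further group passed the threshold with the culture as a block and not without it. The SE given are those of the fit without the block, not of the blocked fit that gave the calls. The secreted metabolic regulator ANGPTL4 rose by 1.73 ± 0.35, the angiogenic factor VEGFA by 1.18 ± 0.29, the glucose transporter SLC2A1 by 0.90 ± 0.27 and the glycine and serine enzyme SHMT2 by 0.94 ± 0.28. The proline synthesis enzyme ALDH18A1 rose by 1.55 ± 0.31, and the sterol genes DHCR7 and INSIG1 by 1.46 ± 0.34 and 1.82 ± 0.58. The procollagen protease BMP1 rose by 1.03 ± 0.22, the receptor NOTCH3 by 1.24 ± 0.28, IL6 by 1.36 ± 0.50 and CLDN4 by 2.21 ± 0.79. The histone genes HIST1H2BC and HIST2H2BE rose by 0.81 ± 0.20 and 0.91 ± 0.29. Lower were ID2, an inhibitor of differentiation (-1.19 ± 0.28), SMAD9, which carries BMP signals (-1.68 ± 0.39), the kinase PLK2 (-1.65 ± 0.43), the thioredoxin reductase TXNRD1 (-1.48 ± 0.35), and the nuclear RNA NEAT1 (-1.18 ± 0.24). IL24 and WNT16 were also lower in that fit; WNT16 was listed at 11.3 and 37 with NULL alone, 1.74 and 4.64 with NULL and TGF-beta, 26.4 and 29.7 with RGCC alone and 0 and 0 with RGCC and TGF-beta. The blocked limma adjusted p of this group lay between 0.00569 and 0.0444. Not called in either fit were TIMP1 (0.91 ± 0.26), the cell cycle inhibitor CDKN1A (0.81 ± 0.24), cyclin B1 (CCNB1, -0.083 ± 0.29), CDK1 and RGCC. MMP3, a matrix-degrading protease, was listed at 44.8 and 15.2 with NULL alone, 4.62 and 9.14 with NULL and TGF-beta, 39.2 and 0 with RGCC alone and 50.8 and 12.5 with RGCC and TGF-beta.

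Among the other lists, cholesterol synthesis genes had a median of 0.67, adjusted p = 8.04e-05 and 0.402 with an estimated correlation, and replication-dependent histones 0.71, adjusted p = 0.000654 and 0.438 with an estimated correlation, with 4 higher when adjusted over the list alone. Collagen processing genes had a median of 0.43, adjusted p = 0.00136 and 0.369 with an estimated correlation. Synthesis genes of serine, glycine and proline had 0.44, adjusted p = 0.00931 and 0.466 with an estimated correlation, and protease inhibitors 0.30, adjusted p = 0.0136 and 0.307 with an estimated correlation. BMP pathway and ID genes stood lower, at -1.06, adjusted p = 0.00207 and 0.402 with an estimated correlation, with 2 lower when adjusted over the list alone, and interferon-stimulated genes at -0.35, adjusted p = 0.0324 and 0.438 with an estimated correlation. Mitochondrially encoded genes had a median of 0.36, adjusted p = 0.0196 and 0.706 with an estimated correlation, at 0.81 in culture 1 and -0.078 in culture 2, and turned to -0.019 without culture 1 of RGCC alone. Within set A the medians were 0.27 (0.71) for cholesterol synthesis, 0.47 (0.59) for histones, -1.004 (-0.59) for BMP and ID genes and -0.57 (-0.43) for interferon genes. With quantile normalization the list calls with TGF-beta went from 9 higher and 2 lower to 6 higher and 5 lower. Ribosomal proteins (median 0.24, 0.0551), complement (-0.36, 0.0704) and lipofibroblast genes (-1.13, 0.062) missed the threshold and passed it with the culture as a block, at 0.0499, 0.0449 and 0.0283. With an estimated correlation the blocked adjusted p were 0.621, 0.251 and 0.251. Of 15 alternatives, a list call was lost with its sign kept in 6 for interferon genes, 5 for serine, glycine and proline synthesis, 3 for mitochondrial genes, 2 each for histones and BMP and ID genes, and 1 each for cholesterol synthesis, collagen processing and protease inhibitors.

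**Figure D4:**
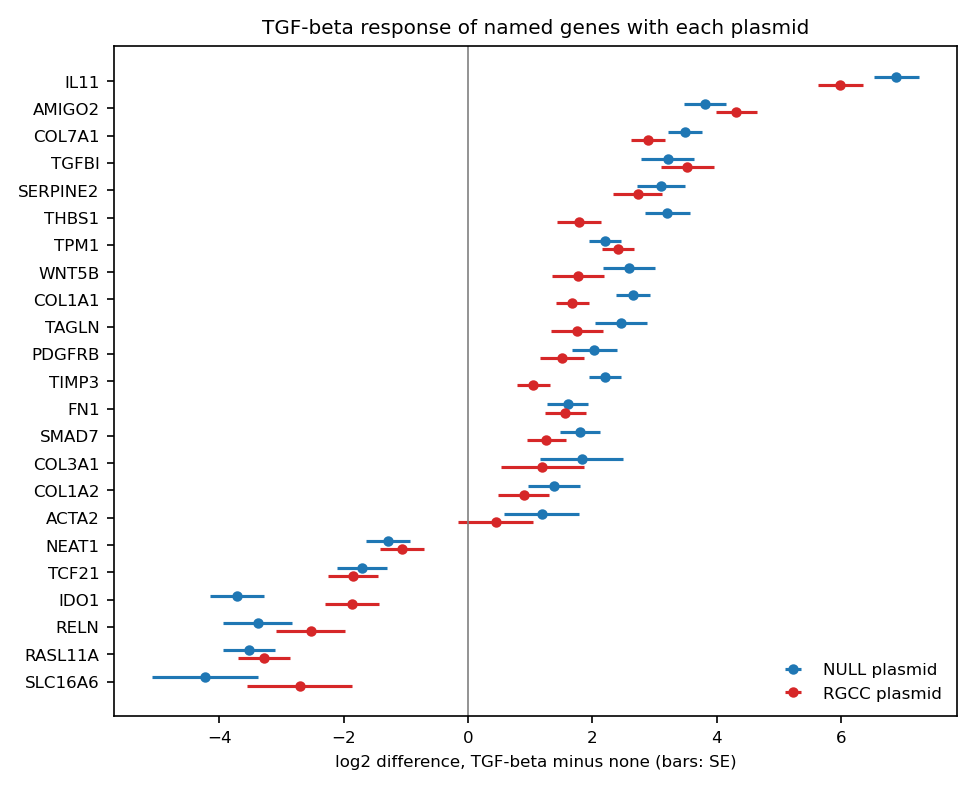
Log2 difference with TGF-beta (x axis, error bars ± SE) of 23 genes (y axis) with the NULL plasmid (blue) and with the RGCC plasmid (red), 2 libraries per group. IL11 lies at 6.89 and 5.99, and COL1A1 at 2.65 and 1.68.

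With the NULL plasmid TGF-beta changed 42 genes, 32 higher and 10 lower, and 178 with the culture as a block; 2102 had an unadjusted p under 0.05 (2801 blocked). IL11 rose by 6.89 ± 0.36, COL7A1 by 3.50 ± 0.27, elastin (ELN), the main protein of elastic fibers, by 4.44 ± 0.44, COL1A1 by 2.65 ± 0.27 and THBS1 by 3.21 ± 0.36. SERPINE2 rose by 3.10 ± 0.39, TIMP3 by 2.21 ± 0.26, TGFBI by 3.22 ± 0.43 and TPM1 by 2.20 ± 0.26. PTHLH, a parathyroid hormone-like hormone, rose by 4.55 ± 0.61, the olfactomedin OLFM2 by 4.12 ± 0.50 and LRRC17 by 3.96 ± 0.48. IDO1 fell by 3.72 ± 0.44, RASL11A by 3.52 ± 0.42 and TNFRSF11B, a decoy receptor of the TNF family, by 2.65 ± 0.37; IL24 and WDCP were lower, IL24 being listed at 0 in both NULL libraries with TGF-beta. The limma adjusted p lay between 0.000474 and 0.04. Called with the culture as a block alone were TAGLN (2.46 ± 0.42), calponins CNN1 (3.78 ± 0.67) and CNN2 (2.41 ± 0.38), COL3A1 (1.83 ± 0.67), SMAD7 (1.80 ± 0.32), the Wnt genes WNT5B (2.59 ± 0.42) and FZD8 (2.03 ± 0.47), LIF (3.21 ± 0.50) and INSIG1 (2.12 ± 0.87). So were PDGFRB (2.03 ± 0.36), DACT3 (5.09 ± 0.86) and CLDN4 (2.58 ± 1.18), each of them higher. COL10A1 was called higher in that fit too (adjusted p = 0.0225). Lower in that fit alone were the lysosomal protease CTSL (-1.49 ± 0.25), SLC16A6 (-4.23 ± 0.85), IFIT2 (-2.32 ± 0.53), the superoxide dismutase SOD2 (-1.64 ± 0.38), the NRF2 targets AKR1C1 (-2.06 ± 0.49) and TXNRD1 (-1.89 ± 0.48), the chaperone HSPA8 (-1.46 ± 0.46) and the lipid-droplet protein PLIN2 (-2.04 ± 0.94). The SE of the genes called in the blocked fit alone are those of the fit without the block. The count was 2 without culture 1 of NULL alone, 4 without culture 2 of NULL alone, 9 without culture 1 of NULL with TGF-beta, 25 without culture 1 of RGCC alone and 26 without culture 2 of RGCC alone.

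With the RGCC plasmid, a comparison of library set C with set B, TGF-beta changed 11 genes, 9 higher and 2 lower, and 21 with the culture as a block; 737 had an unadjusted p under 0.05 (1073 blocked). IL11 rose by 5.99 ± 0.36, AMIGO2 by 4.32 ± 0.34, TGFBI by 3.53 ± 0.43, the semaphorin SEMA7A by 3.03 ± 0.37, COL7A1 by 2.90 ± 0.27 and TPM1 by 2.41 ± 0.26, while RASL11A fell by 3.29 ± 0.42; adjusted p lay between 0.00148 and 0.0487. ARSI was higher and LMNB1 lower, both listed at 0 in some libraries. SERPINE2 (2.73 ± 0.39), PMEPA1, a feedback inhibitor of SMAD signaling (2.69 ± 0.66), and DACT1 (4.62 ± 1.08) were called in the blocked fit, and so was COL10A1 (adjusted p = 0.0354). COL1A1 differed by 1.68 ± 0.27, FN1 by 1.57 ± 0.33 and SMAD7 by 1.26 ± 0.32 without passing. The count was 2 without culture 1 or 2 of NULL alone, 7 without culture 1 of NULL with TGF-beta, 5 without culture 2 of NULL with TGF-beta and 1 without culture 1 or 2 of RGCC with TGF-beta.

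Whether RGCC altered the response to TGF-beta was tested as the interaction, which cannot be separated from the library sets. By limma no gene passed, with or without the culture as a block; an unadjusted p under 0.05 was reached by 594 genes (912 blocked), against 674 expected by chance. COL1A1 differed between the responses by -0.97 ± 0.39 and ACTA2 by -0.74 ± 0.85, neither past the threshold, and FAT3 (-5.91 ± 0.84), TECPR1 (-3.58 ± 0.63), the calcium-binding RCN3 (-2.56 ± 0.46) and ZFAT (-3.24 ± 0.87) had adjusted p of 0.612 to 0.974. The other genes with the smallest p (LMNB1, ARSI, HOXA4, PANX2, IL24, GMEB2 and FAN1) were listed at 0 in some libraries. PANX2, a pannexin channel, was listed at 0 and 0 with NULL alone, 32.3 and 30.5 with NULL and TGF-beta, 20 and 16.5 with RGCC alone and 0 and 2.63 with RGCC and TGF-beta. Of the lists, the contractile genes had 18 of 21 members negative (median -0.52), ribosomal proteins a median of 0.54 and interferon-stimulated genes 0.49, at camera adjusted p of 0.00551, 0.0062 and 0.019; with an estimated correlation the adjusted p were 0.875, 0.987 and 0.875. With the culture as a block the calls were joined by histones (adjusted p = 0.0139), matrix proteins (0.0237) and NRF2 targets, the antioxidant response genes (0.045). These too were lost with an estimated correlation, at blocked adjusted p of 0.718 for each. Of 14 alternatives, the contractile list lost its call in 2 and the ribosomal and interferon lists in 4 each. The number of such lists was 1 without culture 1 of NULL alone, 8 without culture 1 of NULL with TGF-beta, 0 without culture 2 of NULL with TGF-beta and 5 without culture 2 of RGCC with TGF-beta.

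The 126 genes changed by TGF-beta had a smaller median response with RGCC, a difference that cannot be separated from the library sets. Signed by their direction, their median response was 2.19 with NULL and 1.61 with RGCC; the median interaction was -0.41, smaller with RGCC for 100 genes (79.4%; by limma's fry, which allows for correlation between genes, p = 0.0295). The 98 genes that rose had a median interaction of -0.41 (camera p = 1.34e-08, 0.0606 with an estimated correlation, fry p = 0.0583) and the 28 that fell 0.38 (0.000786, 0.0639 and 0.0472). RGCC itself, over both states, gave -0.44 in the risen genes (camera p = 3.18e-14, 0.0485 with an estimated correlation). In the fallen genes it gave 0.35 (camera p = 3.54e-05, 0.0966 with an estimated correlation). The latter turned to -0.23 without culture 2 of RGCC with TGF-beta and to -0.47 without the shallowest libraries. Over the 126 genes, signed, the RGCC medians in cultures 1 and 2 were -0.14 and -0.28 without TGF-beta. With TGF-beta they were -0.73 and -0.44, so the value over both states came largely from TGF-beta-treated cells. The 126 genes were chosen on the TGF-beta effect in the same libraries, and noise shared by both effects can lower these RGCC medians. The camera p-values for RGCC in the risen and fallen genes do not account for that choice. Over genes chosen in the other culture, the signed medians over both states were -0.33 in culture 1 and -0.24 in culture 2. With the culture as a block the median interaction was -0.36 and the call ended (p = 0.086 over 305 genes by fry with the genes' correlation allowed for). The median by culture was -0.64 in culture 1 and -0.22 in culture 2. Without the shallowest libraries, culture 1 of NULL with TGF-beta and culture 2 of RGCC alone, it was -0.16, over the 16 genes then called. Leaving out a library moved it to -0.20 without culture 1 of RGCC alone and -0.17 without culture 1 of RGCC with TGF-beta. Across genes, which are not independent replicates, the RGCC and TGF-beta effects correlated at r = -0.315. Both effects come from the same libraries, and the shallowest ones enter them with opposite signs, so their noise alone lowers r. No value of r without an effect was computed, so r does not show opposed effects.

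**Figure D5:**
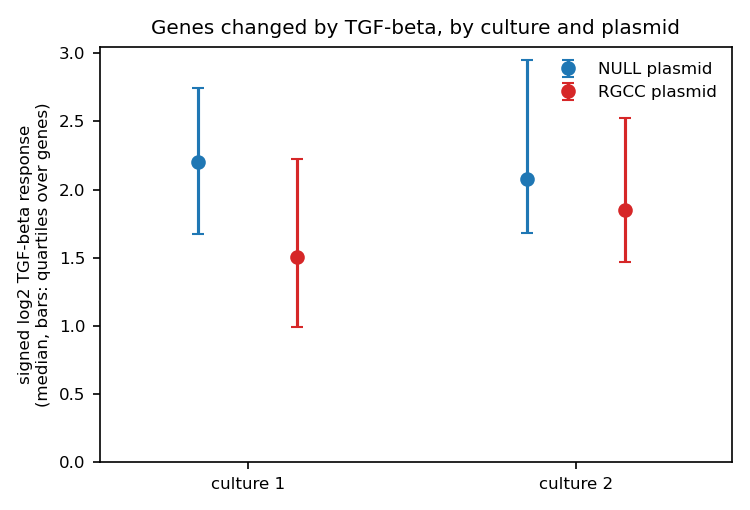
Median response to TGF-beta (y axis, log2, signed by the direction of each gene; bars span the quartiles) of the 126 genes changed by TGF-beta, by culture and plasmid (x axis). In culture 1 the medians are 2.20 with NULL and 1.503 with RGCC, and in culture 2 2.08 and 1.85.

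Lists called in neither main comparison are given as medians with camera adjusted p in parentheses. Matrix-degrading proteases had a median of -0.15 (0.296) with RGCC and 0.49 (0.142) with TGF-beta, inflammatory cytokines and NF-kappaB targets 0.052 (0.911) with RGCC and -0.40 (0.61) with TGF-beta, and genes of the unfolded protein and ATF4 response 0.48 (0.244) with RGCC and 0.18 (0.359) with TGF-beta. The Wnt pathway had -0.44 (0.34) with RGCC and 0.14 (0.82) with TGF-beta, heat shock and metallothionein genes -0.016 (0.608) with RGCC and -0.26 (0.11) with TGF-beta, and NRF2 targets 0.02 (0.654) with RGCC and -0.16 (0.285) with TGF-beta. Immediate early genes had 0.17 (0.0677) with RGCC and 0.074 (0.608) with TGF-beta, complement -0.0017 (0.769) with RGCC and -0.36 (0.0704) with TGF-beta and lipofibroblast genes 0.10 (0.719) with RGCC and -1.13 (0.062) with TGF-beta. Nuclear-retained transcripts had 0.34 (0.16) with RGCC and -0.63 (0.062) with TGF-beta. Markers of other cell types were called in neither comparison apart from the leukocyte list. Epithelial markers had -0.13 (0.608) with RGCC and -0.059 (0.85) with TGF-beta, endothelial markers 0.17 (0.947) with RGCC and 0.25 (0.514) with TGF-beta, and pericyte and smooth muscle markers -0.044 (0.947) with RGCC and 0.10 (0.689) with TGF-beta. Lists called in 1 comparison had, in the other, -0.42 (0.0908) for SMAD targets, -0.30 (0.117) for protease inhibitors, -0.0086 (0.713) for serine, glycine and proline synthesis and -0.29 (0.608) for BMP and ID genes with RGCC. With TGF-beta the medians were 0.016 (0.82) for p53 targets, -0.016 (0.858) for G2/M, 0.31 (0.334) for G1/S, 0.26 (0.0704) for hypoxia, -0.022 (0.85) for fibroblast identity and -0.061 (0.8) for leukocyte markers. Of the mesothelial list, BNC1, a transcription factor gene, was the only member above the minimum (0.73 ± 0.47 with RGCC and -0.17 ± 0.47 with TGF-beta). Among these values the median and the mean had opposite signs for serine, glycine and proline synthesis and pericyte markers with RGCC. They also did for G2/M, p53 targets, the Wnt pathway, fibroblast identity, epithelial, leukocyte and pericyte markers with TGF-beta. The test of endothelial markers with RGCC pointed down where their median was positive.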

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

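The tests on the library sets and the fit without the shallowest libraries were chosen only after the results were seen. By a test of the difference itself, camera with the preset correlation, the effect of RGCC with TGF-beta differed from that without it for contractile and myofibroblast genes (-0.52, median log2), interferon-stimulated genes (0.49) and ribosomal proteins (0.54), and the response to TGF-beta with RGCC from that with NULL for risen genes (-0.41) and fallen genes (0.38). None of these held with an estimated correlation, at adjusted p of 0.875, 0.875 and 0.987 for the lists, p = 0.0606 for risen and 0.0639 for fallen genes, and the contrast cannot be told apart from the library sets. The library sets were drawn from the table entries without a gene name, so calls among these entries are not separate from the sets. Of the 210 table entries without a gene name, 12 were higher and 16 lower with RGCC across both states, 34 higher and 24 lower with RGCC in resting cells, 28 and 22 with TGF-beta across both plasmids, 24 and 38 with TGF-beta and RGCC, and 0 and 3 in the interaction. By limma, none changed with RGCC under TGF-beta (unadjusted p under 0.05 for 13 entries) or with TGF-beta and NULL (16). Both of these comparisons use the NULL with TGF-beta libraries, which fall in sets A and B.

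The response of the 126 TGF-beta-responsive genes was smaller with RGCC. The scaling of the libraries did not account for it, since with quantile normalization the median interaction was -0.41, and neither did choosing genes on noise shared by both effects, since genes chosen in one culture gave -0.33 or lower in the other. Within library set B and culture 2, the RGCC difference over genes chosen in culture 1 was -0.41, but with 1 library on each side this does not exclude the library sets. The shallowest libraries stay open too, since without them the median was -0.16 over 16 genes. A smaller response with the RGCC plasmid is a hypothesis from these data, with the interaction itself not separable from the library sets.

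Of the 14 gene lists that moved with RGCC, 12 were still called with quantile normalization, so they did not rest on the scaling as a whole. In the culture with fewer of them 13 had a median in the called direction, and within library set B 13, but the lists were called on these same libraries, set B has 1 NULL library, and the G2/M, G1/S and mitochondrial lists rested almost wholly on one culture, so neither one culture nor the library sets is excluded. Chance could not be excluded: 3 of the 34 splits of the 8 libraries that can be fitted beside the other factor called as many lists, 14 for the real split and 15 for the highest other. Among the 17 splits with 2 libraries of each culture on a side, the highest other called 13. These 17 splits are too few for a share under 0.05. The interferon median of 0.64 was above that of each other split (highest 0.50), while 2 splits gave a histone median as large and 5 a cholesterol median as large, the real one included. Only these lists were followed over the splits, and they were called on the same libraries. The rank of the interferon median therefore does not exclude chance for that list.

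For the genes called, 2 of the 34 splits gave as many with RGCC, 2 for the real split and 158 for the highest other, so chance could not be excluded for the count. That other split follows the culture and calls many genes, which points to a structure of the samples; with the culture as a block 2 genes were called, and among the 17 splits with 2 libraries of each culture on a side, too few for a share under 0.05, the highest other gave 1. For TGF-beta 1 of 34 splits gave 126 genes, the real one, and the highest other, again the culture split, gave 96. The share over all splits was under 0.05, but they include splits unbalanced for culture, which pairs the samples. Among the 17 balanced splits the highest other gave 0, but these are too few for a share under 0.05. Chance was therefore not excluded by the splits that keep the pairing. For lists moved with TGF-beta 6 of 34 splits gave as many, 11 for the real split and 14 for the highest other, and chance could not be excluded.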

How the results depend on the processing

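Leaving out the shallowest libraries and the term for the library set were chosen after seeing the data. Of the 65 calls of named genes, 65 kept one sign in each alternative run and 6 stayed past the threshold in each: RGCC across both states, IL11, AMIGO2 and COL7A1 with TGF-beta, and IL11 with each plasmid. The set term was not fitted for RGCC in resting cells, TGF-beta with RGCC and the interaction, which it cannot separate from the sets, and elsewhere rests on 1 library on one side. The RGCC gene count moved to 6 with the set term and otherwise stayed at 2 (2 to 3 leaving out a library). In resting cells the RGCC count was 2 with a pseudocount of 8, 2 without a filter, 2 at a mean of 50 and 0 without the shallowest libraries (0 to 4 leaving out a library). With TGF-beta it was 2, 3, 2 and 0 (0 to 24). The TGF-beta count was 305 with the culture as a block, 16 without the shallowest libraries and 41 with the set term (41 to 475). With NULL it was 68 with a pseudocount of 8, 77 at a mean of 50, 178 with the block and 1 without the shallowest libraries (2 to 41), and with RGCC 7, 7 without a filter, 21 with the block and 5 (1 to 15). The interaction gave 0 to 1 genes leaving out a library. The median interaction was -0.36 with the block, not past the threshold, -0.16 without the shallowest libraries, and -0.52 to -0.17 leaving out a library; the effect of RGCC on risen genes was -0.59 to -0.27. Lists moved with RGCC numbered 10 to 15 and with TGF-beta 8 to 14 leaving out a library, the latter 17 without a filter and 4 with the set term. Interaction lists numbered 5 at a mean of 50, 6 with the block and 0 to 8 leaving out a library. Reversed were the RGCC effect on fallen genes (range -0.23 to 0.59 leaving out a library, -0.47 without the shallowest libraries and -0.23 without culture 2 of RGCC with TGF-beta), the serine, glycine and proline list with RGCC (0.32) and the G2/M list with TGF-beta (0.46) without the shallowest libraries, and ribosomal proteins with RGCC (0.10) with the set term. Mitochondrial genes with TGF-beta reversed without culture 1 of RGCC alone (range -0.019 to 0.63 leaving out a library). The cause was not tested, except that a library left out leaves fewer samples and a lone sample is assumed to vary like the other groups. Lists that kept their call in all 15 alternatives were, with RGCC, matrix proteins, collagen processing, histones, interferon and cholesterol genes, and with TGF-beta SMAD targets, matrix and contractile genes. With an estimated correlation each of them but the SMAD targets lost it. No count model was run, since whole reads were not recovered, and depth of 4.57 to 11.8 M protein-coding reads limits low genes.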

Other observations

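The 3 tests on GH1 were chosen only after its values were seen. TGF-beta moved further genes outside the fixed lists and the naming rule, chosen here after their values were seen. Higher were IGFBP3, a carrier of insulin-like growth factor (3.85 ± 0.44, limma adjusted p = 0.00418), the vitamin D receptor VDR (2.94 ± 0.49, 0.0271) and the kinase NUAK1 (2.94 ± 0.36, 0.00622). So were the membrane proteases ADAM12 (2.30 ± 0.38, 0.0269) and ADAM19 (2.37 ± 0.29, 0.00622), the proprotein convertase FURIN, which processes pro-TGF-beta (1.55 ± 0.26, 0.0252), and the growth factor PDGFA (1.46 ± 0.26, 0.0375). The cytoplasmic actins ACTB (1.26 ± 0.24, 0.0483) and ACTG1 (1.15 ± 0.22, 0.0481) were called higher. ACTA2 (0.82 ± 0.42) was not called, but whether its response differed from theirs was not tested. Lower were CITED2, a transcriptional coregulator (-1.86 ± 0.21, 0.00418), RGS4, a regulator of G-protein signaling (-1.56 ± 0.20, 0.0074), and the histamine receptor HRH1 (-2.01 ± 0.25, 0.0066).

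GH1 rose with the RGCC plasmid in fibroblasts, where the NULL libraries held 49.7 ± 2.53 (SD, n = 2) without TGF-beta. Activation of the region around GH1 is argued against, since the 17 tested genes within 500 kb had a median difference of -0.035 (-0.55 to 0.60). Reads from its near-identical copies stay open: GH2, CSH1, CSH2 and CSHL1 together reached at most 0.0413% of GH1 in an RGCC library, but a 0 can be a failed estimate, and reads shared by copies can be assigned to one of them. A candidate explanation is GH1 sequence carried by the plasmid, as growth hormone polyadenylation signals are common plasmid parts; it stays open, since the ratio of GH1 to RGCC was 4.34, 2.4, 2.14 and 2.39 in the 4 RGCC libraries, the highest 2.03 times the lowest. The plasmid's sequence was not used here, and no biological explanation other than activation of the region was tested.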
